A study of Mus musculus with 2 samples.

How the data were processed

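CUT&RUN peak lists of 2 libraries were used, 1 for ELF3 and 1 for NFKB2, from primary renal tubular epithelial cells of wild-type mice treated with TNFα and IFNγ. Each library was its own group, taken from the labels, and both carry the same batch label. IgG is named as the negative control in the series' design text; an IgG peak list was not analysed here.

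Regions were called with MACS2, per the submitters' processing notes, and each library has its own list, with no pooling stated in the labels. The version, the settings, the aligner and the read filters are not given in the sources used here. The deposited lists give for every region a start, an end and 1 summit, a score, a fold and −log10 p and q. The deposited score equals the whole-number part of 10 times −log10 q. The deposited fold is the ratio of summit signal to local background, computed by the authors' caller. The deposited −log10 p and −log10 q refer to the summit. The summit lists repeat the same positions and −log10 q. The lowest −log10 q was 1.02 in the ELF3 list and 1.01 in the NFKB2 list, and neighbouring regions were at least 1001 and 1006 bp apart, so regions as listed are already joined over shorter gaps.

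The submitters' processing notes name the build mm10. The files themselves hold sequence names such as MU069434v1 and MU069435v1, which belong to GRCm39 and not to GRCm38. ELF3 summits were also set against gene ends of a RefSeq gene table of GRCm38.p6 within 500 bp. A single shift of a whole chromosome, of up to 400 kb, gave 4941 pairs of summit and gene end over 20 chromosomes at the best shift of each, against 1974 without a shift and a sum of 1581 for the median shift. With the gene ends mirrored along each chromosome, the chance level for the best shift was 1603 pairs, which the real best shift exceeded on all 20 chromosomes; no shift was the best one only on chromosome 4. The coordinates are therefore printed as deposited, 1-based, and were not joined to that table. The planned shares at promoters, motif shares, promoter genes and gene lists need an annotation or a genome of the files' build, which was not used here, and were not run. By the rule fixed before the data were examined for that case, the text names the 5 regions of highest −log10 q per library, mitochondrial DNA left out, and the 5 shared regions with the best lower rank of both lists. All other regions named were chosen after their values were seen.

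Depth was recovered from the scores. MACS2 scores a summit by the Poisson probability of its fragments given the local background, and its fold adds 1 to both, so the fold and −log10 p together determine a whole number of fragments and a background. A solution with −log10 p within 0.01 (scaled up for values over 100) was found for 100% of the regions in both lists. A fragment was worth 1.00 in the ELF3 list and 0.964 in the NFKB2 list, where the treatment had been scaled down to the control. The lowest background, called the floor, was 1.22 and 1.31 in the caller's scaled units, or 1.22 and 1.36 fragments. It was found at 70.8% of ELF3 and 70.3% of NFKB2 regions. Steps in the background above the floor gave mean fragment lengths of 121 and 129 bp, and from these 10.1 and 10.6 fragments per kb of the genome size set in the caller. The recovered depths rest on this model of the caller. Tested on lists simulated after each library with known values, the recovery returned the fragments and the background of 100% of 66100 and 13875 regions. The overlap functions were right for 100% of 5000 simulated regions under each of 3 definitions.

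Regions were shared when they overlapped by 1 bp or more. Shares have exact Clopper-Pearson 95% intervals and fragment counts exact Poisson ones, both for counting error only. The chance level came from 100 random placements of each region on its own chromosome, within the stretch that holds regions of either list, with a fixed seed; it takes no account of unmappable sequence. Ratios of fragments were divided by the depth ratio of 1.04, with exact binomial intervals. NFKB2 was taken to exceed ELF3 by more than counting error where an exact binomial bound, corrected for the number of ELF3 regions, excluded equal signal. A uniformly weaker copy was modelled with a negative binomial distribution over ELF3 regions at the floor whose NFKB2 regions, if any, were also at the floor, with the ratio set to give as many regions at the listing limit as seen; on a simulated copy of 47344 regions, seen numbers were 1.09 to 1.12 times those computed. That simulated copy was drawn from the same distribution, so it checks the computation and not the model. In the data, each ELF3 region took the overlapping NFKB2 region of most fragments, which the simulated copy leaves out. No p-value was computed, because regions are not replicates. Alternatives planned before the data were examined were −log10 q of 5 and 10 or more, joining of regions within 500 bp, counting every summit, autosomes and X only, equal numbers of regions, overlap of 50% of the shorter region and summits within 100 bp. Alternatives added later were regions at the floor only, regions of 1 list at the floor against all of the other, moving all regions of a chromosome together around it, and other limits for wide regions and for the X share. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.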

Results

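CUT&RUN, in which a nuclease tethered to an antibody releases the DNA around a bound protein, was performed on primary mouse renal tubular epithelial cells treated with the inflammatory cytokines TNFα and IFNγ. The data comprised 2 libraries, 1 with an antibody against ELF3 and 1 with an antibody against NFKB2. ELF3 is an epithelial transcription factor of the ETS family, and NFKB2 is the precursor and subunit of the non-canonical NF-κB pathway. Both libraries came from wild-type kidney cells of the same batch. The ELF3 library had 10.1 fragments per kb of the genome size set in the caller and the NFKB2 library 10.6, as recovered from the peak scores, so depth differed by a factor of 1.04. With 1 library per antibody there was no replicate error, and no difference between the antibodies has a replicate check. The 95% intervals given for shares (exact binomial) and for fragments (exact Poisson) cover counting error only. Regions are given by the deposited coordinates, which use sequence names of GRCm39 although the submitters' processing notes name mm10, and no gene was assigned to any region.

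The first comparison asked how many regions each factor occupied in the treated cells. ELF3 was found at 68319 regions covering 47.1 Mb, and NFKB2 at 14217 regions covering 7.31 Mb, a 4.81-fold difference in number. ELF3 regions were wider, with a median of 418 bp (quartiles 245 and 874 bp) against 329 bp (223 and 601 bp) for NFKB2. The widest ELF3 region reached 89669 bp and the widest NFKB2 region 23470 bp. At its summit the median ELF3 region held 22 fragments (quartiles 14 and 36) and the median NFKB2 region 16 (13 and 22). Within its own list, the median deposited fold over local background was 9.44 for ELF3 and 6.69 for NFKB2. Autosomes and the X chromosome carried 68241 of the ELF3 regions and 14183 of the NFKB2 regions. With only regions of −log10 q of 10 or more the ratio of the numbers rose to 8.38, since 45058 ELF3 and 5378 NFKB2 regions remained.

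The second comparison asked whether the factors occupied the same places. Almost every NFKB2 region lay on an ELF3 region: 13769 of 14217 overlapped one by 1 bp or more (96.8%, 95% interval 96.5 to 97.1). NFKB2 regions placed at random on the same chromosomes overlapped ELF3 regions in 3.44% of cases on average (3.02 to 3.83% over 100 placements). In the other direction 13431 of 68319 ELF3 regions overlapped an NFKB2 region (19.7%, 19.36 to 19.96), against a random mean of 0.714% (0.625 to 0.812%). Summits of the NFKB2 regions that overlapped ELF3 lay a median of 41 bp from the nearest ELF3 summit (quartiles 16 and 98 bp), and 75.6% of them lay within 100 bp. When the ELF3 list was cut to its 14217 regions of highest −log10 q, 53.4% of NFKB2 regions and 51.5% of ELF3 regions overlapped, against random means of 1.01% and 0.993%.

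Overlap rose with the strength of the region in both libraries. Among ELF3 regions, NFKB2 was present at 2.95% of the lowest quintile of −log10 q, at 12.3% of the middle quintile and at 52.3% of the highest quintile (51.4 to 53.1). Among NFKB2 regions the share on ELF3 went from 91.8% in the lowest quintile to 99.2% in the highest. Overlap rose with width too, from 2.02% in the narrowest quintile of ELF3 regions to 43.8% in the widest, and from 94.8% to 98.3% for NFKB2. Strength and width were not separated. ELF3 regions shared with NFKB2 had a median width of 909 bp and 43 fragments at the summit. The 54888 ELF3 regions without NFKB2 had a median of 345 bp and 19 fragments. The 448 NFKB2 regions without ELF3 tended to be weaker, with a median of 12 fragments (quartiles 10 and 15) against 16 (13 and 22) in the shared ones.

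**Figure D1:**
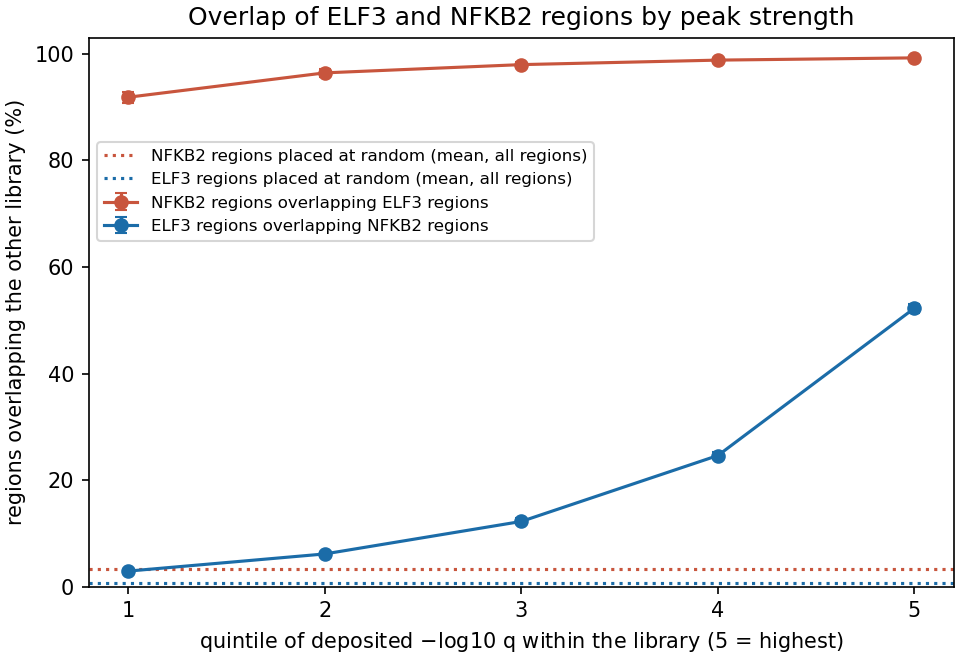
Share of regions (%) of each library that overlapped a region of the other library by 1 bp or more, by quintile of the deposited −log10 q within the library; bars are exact 95% binomial intervals and dotted lines the mean of 100 random placements of all regions. The ELF3 curve rises from 2.95% to 52.3%, and the NFKB2 curve stays at 91.8% or above.

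Strong ELF3 regions without NFKB2 were frequent, whereas strong NFKB2 regions without ELF3 were almost absent. The counts were taken over regions whose local background was at the lowest level of the library, called the floor here. Of 6021 such ELF3 regions with 50 or more fragments, 2465 had no NFKB2 region (40.9%, 39.7 to 42.2), and of 467 with 100 or more fragments 97 had none (20.8%, 17.2 to 24.7). Of 2917 such NFKB2 regions with 20 or more fragments, 16 had no ELF3 region (0.549%, 0.314 to 0.889). None of the 147 NFKB2 regions with 50 or more fragments lacked one (upper limit 2.48%).

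In shared regions the ELF3 signal was usually the higher one. Each of the 13769 shared NFKB2 regions was paired with the ELF3 region of most fragments that it overlapped, and fragments were adjusted for the depth ratio. The median NFKB2 over ELF3 ratio was 0.388 (quartiles 0.272 and 0.561). NFKB2 was higher in 825 pairs (5.99%) and more than 2-fold higher in 76, while it was more than 2-fold lower in 9413. Across regions, which are not independent replicates, Spearman's rho of the fragments was 0.433. Only regions listed for NFKB2 enter these pairs, so regions with weaker NFKB2 signal are left out of the ratio.

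**Figure D2:**
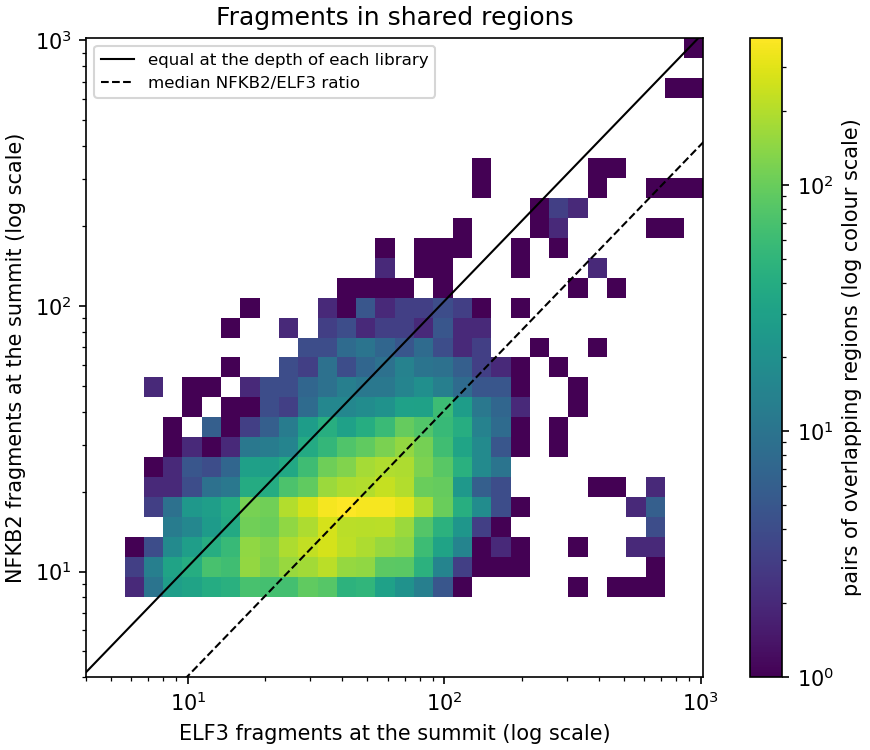
Fragments at the summit of shared regions, ELF3 on the x axis and NFKB2 on the y axis (both log scales), with colour for the number of pairs in each square; 33 pairs with 1024 or more fragments lie beyond the axes. The solid line marks equal signal at the depth of each library and the dashed line the median ratio of 0.388; most pairs lie below the solid line.

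The shared regions with the highest NFKB2 over ELF3 ratio were taken among the 8689 pairs at the floor in both libraries, after their values were seen. Their low ELF3 counts follow in part from that choice. The intervals of the ratios are for single regions and make no allowance for it. With a correction for the number of ELF3 regions, NFKB2 exceeded ELF3 beyond counting error in 7 of the 8689 pairs. The shared regions named next were ranked by ratio, not by that bound, and not all of them pass it. On chromosome 2 at 40445840 to 40447296, NFKB2 had 85 fragments and ELF3 14, a ratio of 5.81 (3.28 to 11.1). On chromosome 6 at 99854820 to 99855285 the counts were 46 and 11 (ratio 4.004, 2.04 to 8.57). A region on chromosome 8 at 95505748 to 95506132 had 33 and 8 fragments, and 1 on chromosome 11 at 54852332 to 54854121 had 57 and 15. The NFKB2 regions of highest −log10 q at the floor that had no ELF3 region were at chromosome 12, 110864572 to 110864985, with 43 fragments (31.1 to 57.9), and chromosome 11, 53709575 to 53710046, with 41.

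The regions of highest −log10 q in each list were sequences with a raised local background. The highest ELF3 region outside mitochondrial DNA lay on chromosome 17 at 40153880 to 40159729, with 4886 fragments and a fold of 44.3 over a background 89.3 times the floor. It was followed by bases 1 to 15878 of the unplaced sequence MU069435v1 (3672 fragments, fold 52.8), chromosome 9 at 123290854 to 123291264 (3486, fold 45.0), chromosome 3 at 5925388 to 5925873 (3438, fold 39.3) and bases 23484 to 31129 of MU069435v1 (3394, fold 33.8). For NFKB2 the first region outside mitochondrial DNA was on chromosome 1 at 24650624 to 24655256, with 1628 fragments, a fold of 9.03 and a background 132 times the floor. The next were chromosome 12 at 97028204 to 97028565 (1015 fragments), chromosome 2 at 22477312 to 22480524 (628), chromosome 17 at 40153887 to 40159722 (1169) and chromosome 11 at 108902468 to 108902943 (1095). Mitochondrial DNA held 1 region in each list, with 4275 ELF3 and 4737 NFKB2 fragments. The 5 shared regions ranking best in both lists were the one on chromosome 17, the ones on chromosome 11 at 108902465 to 108902950, on chromosome 16 at 57211483 to 57212061 and on chromosome 9, and the first one on MU069435v1, in ELF3 coordinates. A background of 10 or more times the floor was found at 71 ELF3 and 70 NFKB2 regions, which took 17 and 16 of the 20 highest places.

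At the floor, where the control signal was not raised, other regions led the lists; they too were chosen after their values were seen. The strongest NFKB2 region was on chromosome 10 at 95913388 to 95913745, with 237 fragments (208 to 269) and 306 for ELF3. On chromosome 13 at 102709293 to 102710580 NFKB2 had 212 fragments and ELF3 110, and on chromosome 8 at 71316053 to 71318990 NFKB2 had 180 and ELF3 84. Chromosome 4 at 79921005 to 79922217 had 208 NFKB2 and 234 ELF3 fragments. ELF3 regions without any NFKB2 region included chromosome 8 at 3804386 to 3804576, with 448 fragments (407 to 491), and chromosome 1 at 190853125 to 190853323, with 403. Both were narrow for their counts, at 191 and 199 bp, while ELF3 regions without NFKB2 had a median width of 345 bp.

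The 5 ELF3 regions of highest −log10 q at the floor lay in groups of wide regions on chromosome 13. Of the 10 ELF3 floor regions with most fragments, 6 lay in the groups described here. Of 26 ELF3 regions over 10 kb on autosomes and X, 17 lay in 3 groups of 3 or more, 2 on chromosome 13 and 1 on chromosome 3. Wide regions were joined into a group over distances of up to 1 Mb. The group at chromosome 13, 21893504 to 22239204, had 7 wide regions, 75.9% of its length within ELF3 regions and up to 656 fragments at a summit. The group at chromosome 13, 23607562 to 23949068, had 7 wide regions, 87.8% of its length covered and up to 657 fragments, in the region from 23832405 to 23903822. The group at chromosome 3, 96124928 to 96472198, had 3 wide regions, 26.0% of its length covered and up to 208 fragments. Its wide regions lay at 96124928 to 96136127, 96142411 to 96159657 and 96461623 to 96472198. They were therefore at its ends, and the group was not a continuous wide stretch. NFKB2 regions covered 1.08%, 3.67% and 3.09% of these groups, with at most 20, 21 and 31 fragments. This was above the average over autosomes and X, where NFKB2 regions covered 0.282% of the stretch with regions. Their density was 36.7 per Mb in the groups against 5.53 per Mb. Most of that stretch holds no ELF3 region, however. Relative to ELF3 cover, NFKB2 cover was lower in the groups, 27.0 kb beside 652 kb of ELF3. Over the whole lists it was 7.31 Mb beside 47.1 Mb. The groups were chosen for their wide ELF3 regions, which raises ELF3 cover there. The lower ratio follows in part from that choice. An NFKB2 region overlapped 12 of the 17 wide ELF3 regions inside the groups and all 9 outside them. The size limit and the groups were set after the values were seen.

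**Figure D3:**
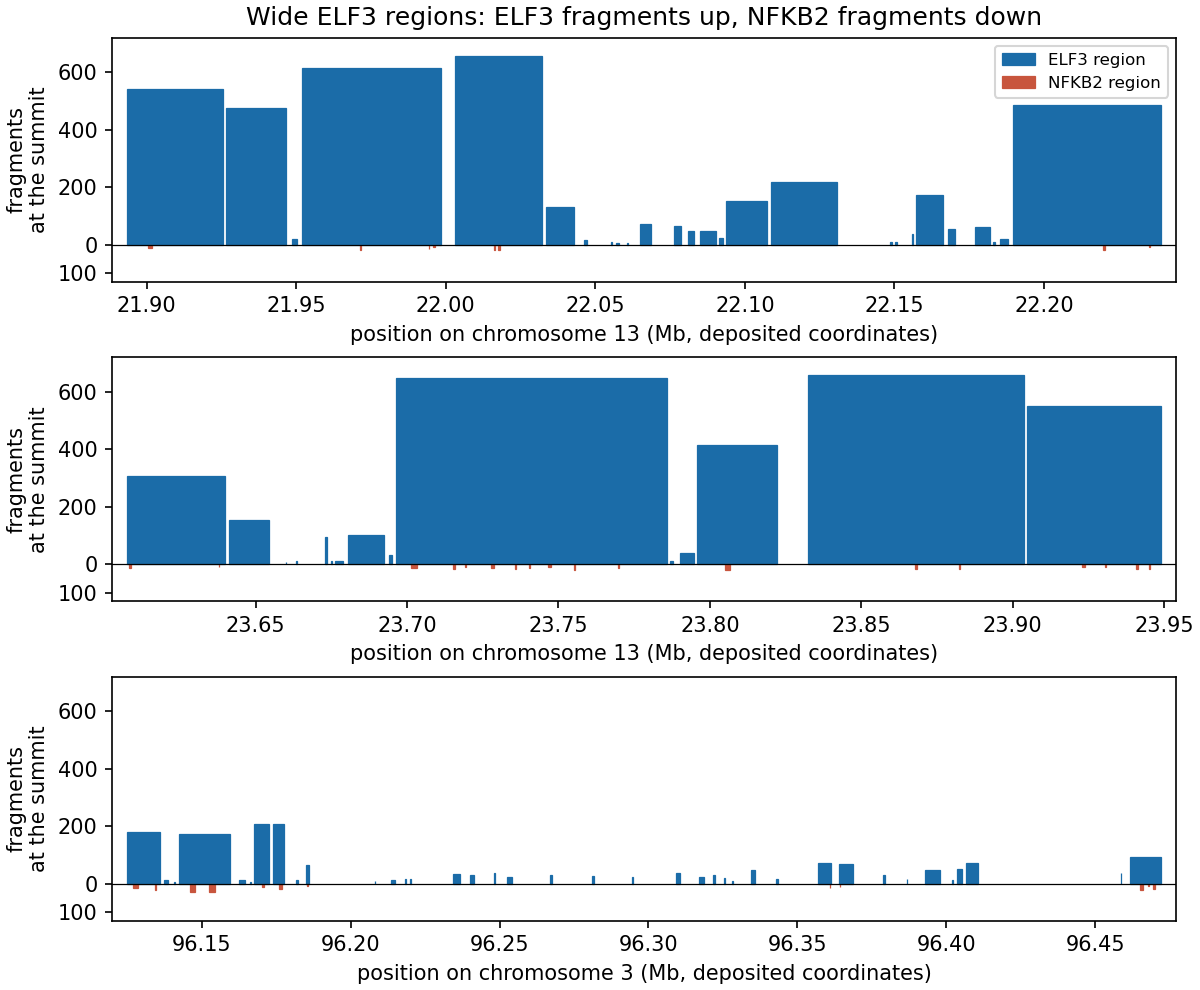
Regions of ELF3 (blue, upward) and NFKB2 (red, downward) in the 3 groups of wide ELF3 regions, by deposited coordinate in Mb; bar width is the extent of the region and bar height the number of fragments at its summit only, not a profile along it. ELF3 reaches 656, 657 and 208 fragments in the 3 groups and NFKB2 at most 20, 21 and 31.

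Both factors differed in how their regions were spread over chromosomes. Chromosome 11 carried 8.51% of NFKB2 regions on autosomes and X (8.06 to 8.98) and 5.96% of ELF3 regions (5.78 to 6.14), or 10.2 and 34.2 regions per Mb. Chromosome 13 carried 4.51% of NFKB2 regions (4.18 to 4.87) and 5.81% of ELF3 regions (5.63 to 5.99). The NFKB2 share had an interval apart from and above that of ELF3 on chromosomes 4, 8, 11 and 19, and apart from and below it on chromosomes 1, 3 and 13, both against all ELF3 regions and against the 14217 ELF3 regions of highest −log10 q. The X chromosome held few regions of either factor, 9.39 ELF3 and 0.750 NFKB2 regions per Mb, while the lowest autosomal values were 23.8 and 4.16 on chromosome 14. The X share of NFKB2, 0.867% (0.721 to 1.03), was below the 2.26% of all ELF3 regions, but its interval met that of the ELF3 regions of highest −log10 q, 1.15% (0.979 to 1.34).

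**Figure D4:**
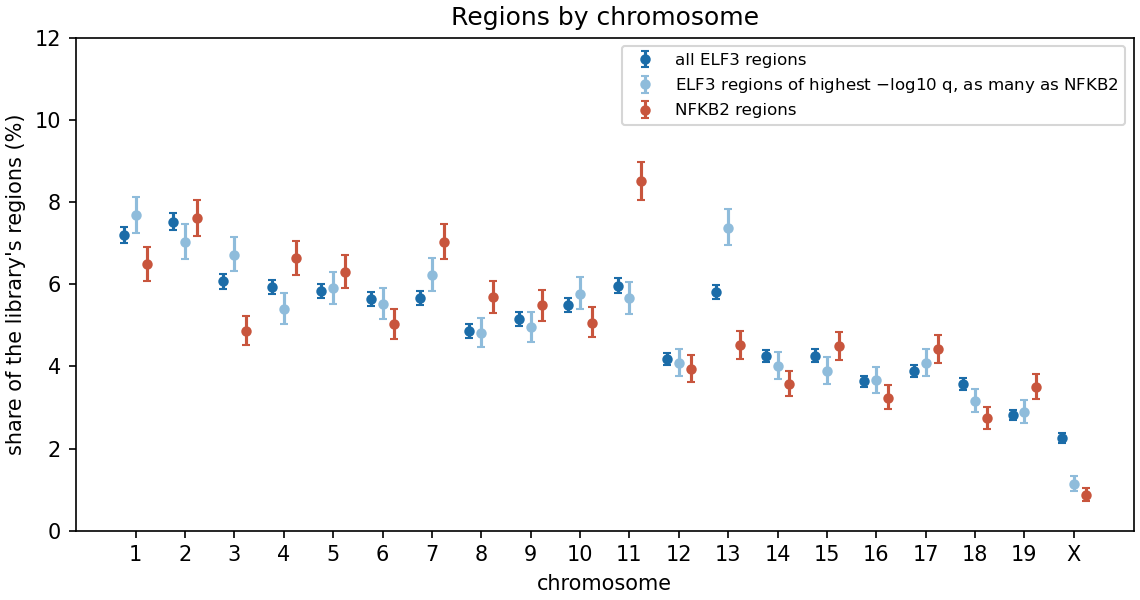
Share of the regions on autosomes and X (%) that lay on each chromosome, for all ELF3 regions, the 14217 ELF3 regions of highest −log10 q and the NFKB2 regions; bars are exact 95% binomial intervals. NFKB2 stands above both ELF3 sets on chromosome 11, at 8.51%, and below both on chromosome 13, at 4.51%.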

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

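Settings that concern the floor, and all those for the X share and the wide regions, were chosen after the data were seen, the others before. Counts stayed within 1.5 times of 68319 and 14217 under every setting run except −log10 q of 10 or more, which left 45058 ELF3 and 5378 NFKB2 regions, a ratio of 8.38; fewer regions pass by construction. Joining regions within 500 bp and counting every summit could change no count, since all gaps were 1001 bp or more and each region had 1 summit. The NFKB2 share on ELF3, 96.8%, was 97.4% at −log10 q of 5 or more, 95.9% with 50% of the shorter region, 73.2% with summits within 100 bp, 87.0% with both lists at the floor and 53.4% with equal numbers. The ELF3 share on NFKB2, 19.7%, was 16.5% and 11.5% at −log10 q of 5 and 10 or more, 15.2% by summits, 17.7% at the floor and 51.5% with equal numbers. Equal numbers, the floor in both lists and the −log10 q limits, which cut both lists, shorten the partner list by construction. The −log10 q limits also drop the weaker counted regions. The rules of 50% of the shorter region and of summits within 100 bp are stricter by construction. How much of each move these account for was not tested. Leaving out the joining and the summit count, 15 of 28 such values stayed within their limits. The settings for the X share and the wide regions on chromosome 13 moved 8 of 15 values. Alternatives for promoters, motifs, promoter genes and gene lists were not run. Weak regions are not listed: the fewest fragments at the floor were 6 in the ELF3 list and 8 in the NFKB2 list, so absence from a list is not absence of binding. The limit was higher for NFKB2 although its library was 1.04 times as deep, so the numbers of regions are compared at unlike fragment limits.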

Other observations

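All tests in this part were chosen after the results were seen, apart from the random placements, which were planned.

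NFKB2 cover of the wide ELF3 regions varied between regions. Over the 9 wide regions outside the groups it had a median of 74.0% of the region's length, with a range of 3.67 to 91.5%. On chromosome 11, ELF3 covered 86466495 to 86479037 with 113 fragments at the summit, and NFKB2 covered 86.9% of it. On chromosome 5, NFKB2 covered 79.3% of 104580706 to 104591130 but 42.9% of 142798951 to 142809522. The lowest values were 21.4% on chromosome 19 at 44735971 to 44746503 and 3.67% on chromosome 13 at 111937363 to 111948102. Inside the groups, NFKB2 covered 0 to 7.21% of each of the 14 wide regions on chromosome 13 and 18.3 to 25.1% of each of the 3 on chromosome 3.

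The groups of wide ELF3 regions on chromosomes 13 and 3 had a median of 415 fragments at the wide summits, against 21 over all ELF3 regions at the floor. NFKB2 regions were 6.64 times denser in the groups than over autosomes and X. Relative to ELF3 cover, NFKB2 cover was lower in the groups, 27.0 kb beside 652 kb, against 7.31 Mb beside 47.1 Mb over the whole lists. The groups were chosen for their wide ELF3 regions, so the lower ratio follows in part from that choice. Raised control signal would lift the local background there, but the median background of the 17 wide regions was 1.00 times the floor, and the highest 1.62 times. Extra copies of these stretches, as the whole cause, would raise a control from the same cells about as much as ELF3. The median ELF3 count at the wide summits was 19.8 times that over ELF3 regions at the floor, far above that highest value of 1.62. These are unlike measures, 1 of fragments at summits and 1 of local background. Each wide region counts by its highest summit, which can raise the first, so the comparison is rough. That the control came from the same cells is assumed, since the sources used here do not say which control entered the peak calling. A hypothesis is that the groups are the clusters of replication-dependent histone genes, since the gene table of GRCm38.p6, used for gene order only, has runs of 5 or more neighbouring histone genes on the same chromosomes, 2 on chromosome 13 with 22 and 31 genes and 1 on chromosome 3 with 10; all 3 groups lie on those chromosomes. The number of groups rests on joining wide regions over distances of up to 1 Mb. Positions were not compared, and whether ELF3, another protein recognised by the antibody or a feature of highly transcribed chromatin gives the signal stays open.

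Fewer NFKB2 than ELF3 regions were listed although the depth of the NFKB2 library was 1.04 times that of the ELF3 library, which argues against lower depth. A copy of the ELF3 profile weaker by 1 ratio at all regions, with counting error in both libraries, would put 40 or more NFKB2 fragments at 11.0 to 96.8 of 47344 ELF3 regions at the floor, depending on the listing limit assumed (8 to 20 fragments), but 273 had as many. Of 428 such regions with 100 or more ELF3 fragments, the copy would leave 1.70 without NFKB2 at a limit of 8, against 97 seen. NFKB2 exceeded ELF3 beyond counting error in 31 of 13769 shared regions, 7 of them among the 8689 at the floor in both. Above the floor, fragments at the summit include raised local background. The pairs outside the 8689 therefore need not show more NFKB2 binding. A ratio that varies between regions was not excluded. Fewer bound sites and a weaker NFKB2 antibody cannot be told apart with 1 library per antibody: the median fold of 6.69 is taken over listed NFKB2 regions only and does not separate them.

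NFKB2 regions lay almost all within ELF3 regions. Random placement against the full ELF3 list gave at most 3.83% overlap over 100 placements, far below 96.8%. Moving all regions of a chromosome together gave at most 3.83% too. Both argue only against random positions with a list of that length. With the ELF3 list cut to its 14217 regions of highest −log10 q the share was 53.4%, against a random mean of 1.01%. How nearly complete the overlap was therefore depended on the length of the ELF3 list. Sequences with raised control signal do not account for the overlap, since 96.8% of the NFKB2 regions at the floor overlapped ELF3. Open chromatin cut by the nuclease whatever the antibody remains a candidate explanation beside shared binding, because Spearman's rho of the fragments in shared regions at the floor, 0.402, is neither near 0 nor near 1 and no accessibility data were analysed here.

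The same control library appears to lie behind both lists. The NFKB2 over ELF3 depth ratio from the floor and the fragment length was 1.0443207, and the ratio required if 1 control of 1 size scaled both libraries was 1.0443213. The series' design text names IgG as negative control without saying that it entered the peak calling.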
